A study of Homo sapiens with 12 samples.

How the data were processed

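Polyadenylated RNA of MCF7 cells, an estrogen receptor-positive human breast cancer cell line, was sequenced in 12 libraries that the labels place in 4 groups of 3 replicates. Cells were exposed 24 h after seeding, per the labels' protocols, to 1 µM benzo[a]pyrene or to 5 Gy of ionizing radiation, or were left untreated, and each exposure has its own untreated control group. The exposure time was 120 h and the replicates were 3 independent experiments, per the design text. Libraries were made with a stranded mRNA kit and read in 150 cycles from both ends, per the labels.

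The deposited values are raw counts of reads per gene, not normalized. The authors counted them over the exons of each gene with featureCounts 1.6.5 in the reverse-stranded setting (strand setting 2) on Ensembl release 94 of GRCh38, per the file headers. The command in the headers holds no option for counting fragments, multi-mapped reads or reads that overlap several genes, so reads shared by near-identical genes or by overlapping exons on the same strand are left out of the counts. STAR 2.7.3a, Subread and DESeq2 are named in the submitters' processing notes. Trimming is not given in the sources used here. Each file lists 58735 genes with the coordinates and exonic length used here. All 58735 identifiers were found in GENCODE release 29, the matching annotation, from which GC content was taken. A current symbol was found for 58207 of them, and the others kept their GENCODE name. No column of another sample was present.

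Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given (minimum count 10, minimum total count 15), which left 16943 genes. Library sizes were scaled by TMM factors. One quasi-likelihood model with a mean per group was fitted to all 12 libraries (glmQLFit, 8 residual degrees of freedom), and 4 contrasts were tested with glmQLFTest, all two-sided: benzo[a]pyrene against its control, radiation against its control, the difference between these changes, and the radiation control against the benzo[a]pyrene control. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and "adjusted p" means this value unless camera is named. Standard errors (SE) of log2 fold changes were approximated as the absolute log2 fold change divided by the square root of the F statistic. For genes with few counts in a group these values can be too small or too large. They are not a reliable measure of precision there. CPM values are counts relative to the TMM-scaled library size, given as mean ± SD with n = 3. Fold changes of genes with few counts in a group depend on the small prior count of the model, and counts are given for some of those genes.

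Gene lists were fixed before the data were examined: 27 lists, 26 of which had the 5 measured members required for a set test. Measured members are those among the genes tested, such as 21 of 34 secretory factors and 18 of 28 epithelial-mesenchymal transition genes. A gene can pass the filter on low counts through 1 group alone. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists within each contrast. The test was repeated with a correlation estimated per list, and with fry. Camera p-values use the preset correlation unless stated, and those of called lists are smaller than with an estimated one. Each comparison names genes by a rule that was also fixed beforehand: 20 key genes of the xenobiotic, p53, proliferation, repair, cytokine and estrogen responses, up to 4 called members of each described list with the largest absolute log2 fold change, and the 6 genes that rose and the 6 that fell most among genes with adjusted p under the threshold, at least 1 CPM on average and no overlap between the groups compared. Names outside this rule are marked as chosen after their values were seen. Overlap of calls was tested by Fisher's exact test, two-sided. The 2 exposures share no control library.

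The scripts were tested on simulated data in which 200 of 16943 genes were changed, besides a short list of genes shifted together for the set test. In the data, from 42.66% (difference of responses) to 65.07% (BaP) of the genes tested were called. The shares that follow therefore check the scripts and do not give the recovery or false calls of the real contrasts. For the benzo[a]pyrene contrast, 58.5% of genes changed by 0.5 on the log2 scale were recovered, 74.2% of those changed by 1 and 98.5% of those changed by 2. For the radiation contrast the shares were 56.2%, 76.9% and 98.5%, for the difference of responses 32.3%, 67.7% and 88.1%, and for the controls 57.1%, 92.5% and 97%. Unchanged genes made up 6.7%, 5.14%, 7.64% and 6.32% of the calls in these contrasts. A GC trend put into 1 group of simulated libraries gave 5581 calls, and 2 remained after the offsets described next.

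Alternatives fixed beforehand were other normalizations, DESeq2 1.42.0, other filters on low counts, the replicate number as a block, only the groups compared, each library left out in turn, a minimum change of 2-fold, removal of mitochondrial genes and of the 10 genes with most counts, and both control groups together as the control. Added after the data were seen were per-library offsets that remove smooth trends with GC content, or with GC content and exonic length, and thinning of all libraries to 24680356 counts. Pairs of replicate libraries of each group differed by more than sampling noise, with chi-square per degree of freedom from 3.02 to 33.6, so no library was counted as a duplicate.

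Totals ranged from 24680356 to 32082418 counts per library. A count of 3 in a library corresponds to between 0.0935 and 0.122 CPM of its total, which is the level that a count of 0 allows. Such limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.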

Results

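Gene expression was measured by RNA-seq in MCF7 cells exposed to benzo[a]pyrene or to ionizing radiation, with an exposure time of 120 h. Benzo[a]pyrene is a polycyclic aromatic hydrocarbon that cells convert into DNA-binding metabolites, and ionizing radiation breaks DNA strands. The design asks how each DNA-damaging exposure changed the expression profile. Each of 4 groups had 3 libraries. Cells given 1 µM benzo[a]pyrene (BaP) gave 29462567 to 31234119 counts per library and their untreated control 30287060 to 32082418. Cells given 5 Gy (IR) gave 26265413 to 27514728 counts per library and the radiation control 24680356 to 30464955. Replicate libraries correlated with Pearson's r of at least 0.9909 across genes within each group. Mitochondrially encoded genes took 6.57% ± 0.712 of the counts in the BaP control, 8.69% ± 0.93 in BaP, 12.9% ± 1.08 in the radiation control and 21.6% ± 1.7 in IR (SD, n = 3). BaP replicate 3 stood apart from its group, with deviations from the group mean that rose with the GC content of the gene (Spearman's rho 0.448 across 16936 genes, which are not independent replicates).

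**Figure D1:**
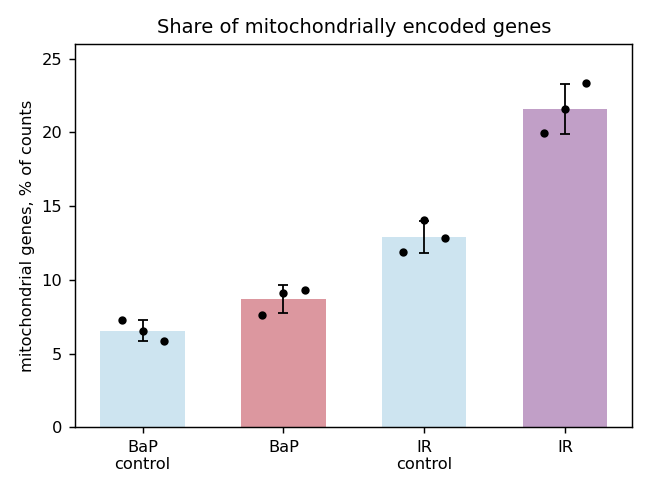
Share of all counts in mitochondrially encoded genes, in percent, for the 12 libraries. Points are libraries, bars are group means and error bars are SD (n = 3). The means were 6.57% and 12.9% in the control groups, 8.69% in BaP and 21.6% in IR.

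After BaP, CYP1A1 and ALDH3A1, targets of the aryl hydrocarbon receptor (AHR), were among the 6 genes that rose most by the rule for named genes. CYP1A1, a cytochrome P450 that oxidizes benzo[a]pyrene (ENSG00000140465, GRCh38 chromosome 15, 74719542 to 74725610), went from 0.255 ± 0.146 to 107 ± 8.08 CPM (SD, n = 3), a log2 fold change of 8.69 (SE 0.271, adjusted p = 1.34e-13), or 9.30 with both control groups together. CYP1B1 rose from 95.9 ± 7.65 to 1120 ± 53.4 CPM, and the feedback repressors AHRR and TIPARP rose by 1.64 (SE 0.11) and 1.72 (SE 0.0771) on the log2 scale. ALDH3A1, an aldehyde dehydrogenase, had 3 counts over the 3 control libraries and 207 over the 3 BaP libraries. Of 13 measured AHR targets 7 rose and 5 fell, with SLC7A5, an amino acid transporter, up by 2.91 (SE 0.0862). The set test called the list higher (camera adjusted p = 3.13e-05), a call lost with an estimated correlation (adjusted p = 0.0873 with an estimated correlation).

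Targets of p53, the transcription factor activated by DNA damage, rose together after BaP: 34 of 39 rose and 1 fell, with a median log2 fold change of 1.30 (camera adjusted p = 1.76e-31). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 99.1 ± 5.87 to 1860 ± 62 CPM (SD, n = 3), a log2 fold change of 4.23 (SE 0.071, adjusted p = 6.81e-16). MDM2, the ubiquitin ligase that degrades p53, rose by 2.17 (SE 0.0632), TP53INP1 by 3.04 (SE 0.0616) and BTG2 by 3.02 (SE 0.105). The stress cytokine GDF15 rose by 4.37 (SE 0.231), with 25091 counts in BaP replicate 3 against 13046 and 12401 in the other BaP libraries. Among apoptosis regulators 12 of 26 rose and 4 fell, with FAS at 2.62 (SE 0.105), TNFRSF10B at 1.33 (SE 0.0488) and BAX at 1.33 (SE 0.0579). BBC3 rose by 2.69 (SE 0.189), and by 1.94 with the GC trend removed, with 2823 counts in BaP replicate 3 against 1681 and 1621 in the other BaP libraries. The call of the apoptosis list (camera adjusted p = 0.0109) was lost with an estimated correlation (adjusted p = 0.217 with an estimated correlation).

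Genes of cell division and DNA synthesis fell in BaP-exposed cells. All 35 measured genes of G2/M and mitosis fell, by a median of -4.04 on the log2 scale (camera adjusted p = 9.2e-143). So did all 38 genes of DNA replication and E2F targets, by a median of -2.47 (camera adjusted p = 2.74e-85). With an estimated correlation each of these lists had a camera adjusted p of 0.000482. MKI67, which encodes the proliferation marker Ki-67, went from 344 ± 33.8 to 15 ± 3.31 CPM (SD, n = 3), a log2 fold change of -4.52 (SE 0.124, adjusted p = 3.24e-14). ASPM, a spindle pole protein, changed by -4.76 (SE 0.0857), the phosphatase CDC25C by -4.53 (SE 0.116). RRM2, a subunit of ribonucleotide reductase, changed by -4.09 (SE 0.084) and MCM10, which starts replication forks, by -4.07 (SE 0.0882). LMNB1, the nuclear lamina protein lamin B1, changed by -3.43 (SE 0.0645).

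DNA repair genes did not move as one group after BaP. In the list of homologous recombination and Fanconi anaemia 32 of 35 genes fell and 2 rose, by a median of -1.85 (camera adjusted p = 2.98e-31), led by RAD54L at -4.15 (SE 0.101) and BRCA2 at -4.06 (SE 0.1). RAD51, the recombinase of this pathway, went from 63 to 5 counts over 3 libraries, an uncertain value because 71.5% of its exonic sequence is shared with another gene on the same strand. Mismatch repair genes fell in 6 of 8 cases. Among them were the exonuclease EXO1 at -4.21 (SE 0.129), MSH2 at -1.51 (SE 0.0683) and MSH6 at -0.96 (SE 0.0724). The call of this list (camera adjusted p = 0.000382) was lost with an estimated correlation (adjusted p = 0.237 with an estimated correlation). Nucleotide excision repair, which removes bulky adducts, had 10 of 21 genes higher and 5 lower and was not called (camera adjusted p = 0.3). Its damage sensors DDB2 and XPC rose by 0.87 (SE 0.0572) and 0.71 (SE 0.0608). Base excision repair had 4 higher and 11 lower of 19, with the glycosylase NEIL3 at -4.87 (SE 0.152) and PARP1 at -1.14 (SE 0.0821). End joining had 4 higher and 9 lower of 13, with POLQ at -3.84 (SE 0.116) and PRKDC, the DNA-dependent protein kinase, at -0.82 (SE 0.0875). PAXX rose by 0.71 (SE 0.169), a call lost with both control groups together (0.14, adjusted p = 0.413) and with GC and length trends removed (0.12, adjusted p = 0.0613). The calls of the base excision and end joining lists (camera adjusted p = 0.0405 and 0.0382) were lost with an estimated correlation (adjusted p = 0.217 and 0.328 with an estimated correlation). Translesion synthesis had 2 higher and 3 lower of 10 and was not called (camera adjusted p = 0.551), with its median and mean of opposite sign. RAD18 changed by -1.43 (SE 0.0831), and POLH, a polymerase of this pathway, was not called (-0.07, SE 0.0871, adjusted p = 0.522).

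In polyadenylated RNA, replication-dependent histone genes rose after BaP in 23 of 29 cases and fell in 2, by a median of 1.84 (camera adjusted p = 4.2e-15). Histone transcripts without a poly(A) tail were not measured, so total histone RNA may have changed otherwise. H4C8 (chromosome 6, 26277609 to 26285638) went from 5.85 ± 1.14 to 116 ± 3.41 CPM (SD, n = 3), and H2BC21 rose by 2.91 (SE 0.083). These are members of a family of near-identical genes, so single members are uncertain. Lysosome and autophagy genes rose in 24 of 28 cases and fell in 1, with the autophagy kinase ULK1 at 1.66 (SE 0.132) and the lysosomal enzyme MANBA at 1.18 (SE 0.0727). CTSD rose by 2.74 (SE 0.155), an uncertain value since 41.7% of its exonic sequence is shared with another gene. Hypoxia and glycolysis genes rose in 19 of 27 cases and fell in 4, with ADM at 2.02 (SE 0.128), the glucose transporter SLC2A1 at 1.76 (SE 0.0701) and the carbonic anhydrase CA9 at -1.93 (SE 0.235). The calls of the lysosome and hypoxia lists (camera adjusted p = 5.26e-07 and 3.13e-05) were lost with an estimated correlation (adjusted p = 0.0873 and 0.0917 with an estimated correlation). The unfolded protein and integrated stress response had 15 higher and 7 lower of 27, with the transcription factor DDIT3 at 1.82 (SE 0.0866) and the serine synthesis enzyme PHGDH at -3.60 (SE 0.0637). Cholesterol synthesis genes fell in 17 of 24 cases and rose in 4, with STARD4 at -1.69 (SE 0.0984) and ACAT2 at -1.64 (SE 0.0746). Cytosolic ribosomal protein genes fell in 39 of 53 cases and rose in 3, with RPS9 at -0.90 (SE 0.0607) and RPL5 at -0.73 (SE 0.0566). The calls of these 3 lists (camera adjusted p = 0.00647, 0.00651 and 0.00148) were lost with an estimated correlation (adjusted p = 0.217, 0.446 and 0.446 with an estimated correlation).

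Secreted factors and hormone targets went both ways after BaP. Among senescence-associated secretory factors 10 of 21 rose and 8 fell (camera adjusted p = 0.141). The cytokine IL6 rose by 3.59 (SE 0.16, adjusted p = 1.36e-11), or 4.75 with both control groups together, IGFBP3 rose by 2.60 (SE 0.153) and SERPINE1 changed by -3.16 (SE 0.325). Interferon response genes had 7 higher and 15 lower of 37 (camera adjusted p = 0.492). OAS3 changed by -2.52 (SE 0.08) and IFI6 by 2.13 (SE 0.149), and MX2 had 12 counts over the control libraries against 1 over the BaP libraries. Estrogen receptor targets had 19 higher and 10 lower of 31 (camera adjusted p = 0.0599), with TFF1 at 1.54 (SE 0.064), PDZK1 at -2.92 (SE 0.128) and MYBL1 at -2.32 (SE 0.0884). ESR1, the estrogen receptor itself, rose by 0.50 (SE 0.0649). NRF2 and oxidative stress genes had 14 higher and 6 lower of 25 (camera adjusted p = 0.0802), with G6PD at 1.20 (SE 0.0589) and OSGIN1 at 1.18 (SE 0.1). Mitochondrially encoded genes had 5 higher and 0 lower of 13 (camera adjusted p = 0.157), with MT-ND1 at 1.13 (SE 0.106). With both control groups together MT-CO1, MT-ND3 and MT-ND5 lost their calls (0.20, 0.052 and 0.14, adjusted p = 0.0663, 0.561 and 0.219).

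By the size of the change alone, the genes that rose most after BaP beside CYP1A1 and ALDH3A1 were the lincRNA ENSG00000271732 (6.49, SE 0.32), RGS22 (5.62, SE 0.152), UGT2B15 (5 counts over the control libraries against 224) and FGB (5.31, SE 0.167). Those that fell most were DMBX1 (-5.36, SE 0.406), NMU (-5.06, SE 0.34), PIF1 (-4.90, SE 0.283), NEIL3, ASPM and KIF14 (-4.70, SE 0.105). NMU was at -4.47 without BaP replicate 1 and -5.68 without BaP replicate 3, and ENSG00000271732 at 5.50 with both control groups together. Few counts underlie the folds of ENSG00000271732 (2, 2 and 0 in the BaP control libraries), DMBX1 (1, 3 and 4 in the BaP libraries) and NMU (0, 3 and 4 there). Over the 16943 genes tested, 11025 were called by edgeR at adjusted p under 0.05, of which 5576 were higher and 5449 lower, and 3463 changed at least 2-fold (1744 higher, 1719 lower). The share of higher calls was 50.6%, and 39.8% with library sizes alone, a scaling with which the median change of all genes was -0.127. Adjusted over the list alone, list counts were the same except for p53 targets (35 higher, 1 lower), NRF2 genes (15 higher, 6 lower) and lysosome genes (25 higher, 1 lower).

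After radiation, genes of the interferon response rose in 36 of 37 cases and fell in 1, by a median log2 fold change of 2.00 (camera adjusted p = 5.28e-42, and adjusted p = 0.000354 with an estimated correlation). IFI6 rose from 6.4 ± 1.23 to 221 ± 14.7 CPM (SD, n = 3), a log2 fold change of 5.10 (SE 0.15, adjusted p = 5.19e-13). XAF1, a pro-apoptotic protein induced by interferon (ENSG00000132530, chromosome 17, 6755447 to 6775647), rose by 5.45 (SE 0.32), IFIT2, which binds viral RNA, by 5.12 (SE 0.187) and SAMD9 by 4.75 (SE 0.175), or 3.87 with both control groups together. IFNL2, which encodes an interferon lambda and has a close copy in IFNL3, had 3 counts over the control libraries and 151 over the irradiated libraries. Senescence-associated secretory factors rose in 17 of 21 cases and fell in 1, by a median of 1.38 (camera adjusted p = 2.28e-09). The chemokine CCL5 rose by 4.34 (SE 0.222) and IL6 by 2.96 (SE 0.284), or 1.796 with both control groups together. TNF had 2 counts over the control libraries and 42 over the irradiated libraries. CXCL8, too low for the test, had 0 counts over the 3 control libraries and 31 over the 3 irradiated libraries, at least 11.4-fold higher against 3 counts over the control group.

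The p53 targets rose after radiation in 30 of 39 cases and fell in 4, by a median of 0.83 (camera adjusted p = 1.82e-18). CDKN1A rose from 114 ± 7.44 to 644 ± 27.3 CPM (SD, n = 3), a log2 fold change of 2.50 (SE 0.0662, adjusted p = 2.85e-13). GDF15 rose by 3.98 (SE 0.227), BTG2 by 2.77 (SE 0.103), TP53INP1 by 2.54 (SE 0.0646), MDM2 by 0.86 (SE 0.0617) and TRIM22, which interferon also induces, by 4.34 (SE 0.386). TRIM22, with 2, 6 and 0 counts in the radiation control libraries, was at 5.63 without radiation control replicate 2 and 3.71 without radiation control replicate 3. Apoptosis regulators had 13 higher and 6 lower of 26, with BBC3 at 2.02 (SE 0.181) and BMF at 1.70 (SE 0.0963). That call (camera adjusted p = 0.0213) was lost with an estimated correlation (adjusted p = 0.264 with an estimated correlation). CYP1A1 rose from 0.102 ± 0.0833 to 10.2 ± 3.64 CPM (SD, n = 3), with 1, 2 and 6 counts in the radiation control libraries. Its log2 fold change was 6.51 (SE 0.395, adjusted p = 1e-09), or 7.39 without radiation control replicate 3 and 5.905 with both control groups together. Of the 13 AHR targets 7 rose and 1 fell, with AHRR at 1.90 (SE 0.112) and CYP1B1 at 1.29 (SE 0.0939). ALDH3A1 had 4 counts over the control libraries and 80 over the irradiated libraries. TIPARP was not called (0.18, SE 0.082, adjusted p = 0.0657), but was called as higher in 6 alternatives. Among these were GC and length trends removed (0.35, adjusted p = 0.000316), the GC trend removed (0.305, adjusted p = 0.0014), only the groups compared (0.20, adjusted p = 0.0204) and without IR replicate 1 (0.23, adjusted p = 0.036). With both control groups together it was at -0.038 (adjusted p = 0.633). The call of that list (camera adjusted p = 0.00147) was lost with an estimated correlation (adjusted p = 0.112 with an estimated correlation).

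Division and replication genes fell after radiation as well. All 35 G2/M genes fell, by a median of -2.12 (camera adjusted p = 4.12e-80), and 37 of 38 genes of DNA replication fell, by a median of -1.54 (camera adjusted p = 1.14e-51). MKI67 went from 296 ± 6.58 to 63.1 ± 3.82 CPM (SD, n = 3), a log2 fold change of -2.23 (SE 0.11, adjusted p = 8.66e-11). ASPM changed by -2.68 (SE 0.0737), the kinase TTK by -2.35 (SE 0.0843), MCM10 by -2.28 (SE 0.079), RRM2 by -2.03 (SE 0.0738) and LMNB1 by -2.26 (SE 0.0614). Homologous recombination and Fanconi anaemia genes fell in 33 of 35 cases and rose in 2, by a median of -1.06 (camera adjusted p = 1.24e-17), led by RAD51AP1 at -2.19 (SE 0.126), FANCB at -2.18 (SE 0.163) and BRCA2 at -2.17 (SE 0.089). RAD51, uncertain as above, went from 44 to 12 counts over 3 libraries.

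Of the other repair lists after radiation, mismatch repair had 6 of 8 genes lower and 1 higher, with EXO1 at -2.06 (SE 0.108), MSH2 at -1.45 (SE 0.0696) and MSH6 at -0.99 (SE 0.0736). Base excision repair had 11 of 19 lower and 1 higher, with NEIL3 at -2.56 (SE 0.122) and PARP1 at -1.11 (SE 0.083). Both calls (camera adjusted p = 0.000957 and 0.00632) were lost with an estimated correlation (adjusted p = 0.269 and 0.0843 with an estimated correlation). End joining, the main route of repair for double-strand breaks, had 7 of 13 lower and 3 higher (camera adjusted p = 0.0505). POLQ changed by -1.37 (SE 0.097), and XRCC6 and XRCC5, which form the end-binding Ku dimer, by -1.02 (SE 0.0721) and -0.98 (SE 0.0778). Translesion synthesis had 6 of 10 lower and 2 higher (camera adjusted p = 0.112), with RAD18 at -1.10 (SE 0.0838), and POLH was not called (0.11, SE 0.0905, adjusted p = 0.301). Nucleotide excision repair had 5 of 21 higher and 7 lower (camera adjusted p = 0.863), with XPC at 0.55 (SE 0.0616), DDB2 at 0.52 (SE 0.0571) and GTF2H2 at -0.97 (SE 0.11).

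In polyadenylated RNA, histone genes rose after radiation in 22 of 29 cases and fell in 2, by a median of 1.27 (camera adjusted p = 2.25e-09). The limit for transcripts without a poly(A) tail holds here too. H4C8 rose by 3.13 (SE 0.109) and H4C5 by 2.91 (SE 0.168), each uncertain as a single gene. Lysosome and autophagy genes rose in 25 of 28 cases and fell in 1 (camera adjusted p = 7.29e-10), with ATG9B at 5.00 (SE 0.195) and GABARAPL1 at 2.46 (SE 0.173). The unfolded protein and integrated stress response had 16 higher and 6 lower of 27, with NUPR1 at 3.14 (SE 0.121) and DDIT3 at 2.21 (SE 0.0839). Cholesterol synthesis had 17 of 24 lower and 2 higher, with ACAT2 at -1.51 (SE 0.0752) and STARD4 at -1.34 (SE 0.0985). CYP51A1 (-0.70, SE 0.278, 79.3% of exonic sequence shared) lost its call without radiation control replicate 1 or 3 (adjusted p = 0.0669 and 0.107) or IR replicate 1 or 2 (adjusted p = 0.102 and 0.141). Ribosomal protein genes had 32 of 53 lower and 3 higher, with RPS7 at -0.58 (SE 0.0622) and RPS9 at -0.53 (SE 0.0602). All 13 mitochondrially encoded genes were higher, by a median of 0.66, with MT-ND1 at 1.00 (SE 0.106) and MT-CO1 at 0.95 (SE 0.11). The calls of these last 4 lists (camera adjusted p = 1.42e-05, 0.00538, 0.00983 and 0.000616) were lost with an estimated correlation (adjusted p = 0.0527, 0.417, 0.563 and 0.417 with an estimated correlation). Hypoxia and glycolysis genes were not called, with 11 higher and 11 lower of 27 (camera adjusted p = 0.747), among them CA9 at -1.37 (SE 0.185) and VEGFA at 1.15 (SE 0.0498). NRF2 genes were not called either, with 10 higher and 10 lower of 25 (camera adjusted p = 0.0667). Among the latter AKR1B10 rose by 2.84 (SE 0.27) and HMOX1, a heme oxygenase, by 2.10 (SE 0.0868). Estrogen receptor targets had 13 higher and 11 lower of 31 (camera adjusted p = 0.359), with MYBL1 at -1.77 (SE 0.0955) and CXCL12 at -1.05 (SE 0.166). In the same list STC2 rose from 109 ± 8.78 to 329 ± 24.5 CPM and IGFBP4 from 38.8 ± 3.78 to 85.5 ± 3.63 CPM (SD, n = 3). ESR1 changed by -0.40 (SE 0.0656) and TFF1 by 0.53 (SE 0.0627), a call lost with GC and length trends removed (0.14, adjusted p = 0.098).

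By size alone, the genes that rose most after radiation were CYP1A1, KRT4 (3 counts over the control libraries against 159), IFNL2, XAF1, IFIT2 and IFI6. Those that fell most were the lincRNA ENSG00000256686 (-2.79, SE 0.232), SPC25 (-2.73, SE 0.101), PTGER2 (-2.71, SE 0.243), HAS2 (-2.70, SE 0.272), ASPM and PRIMA1 (-2.64, SE 0.332). Over the 16943 genes tested, 10877 were called by edgeR, of which 5354 were higher and 5523 lower, and 2951 changed at least 2-fold (2118 higher, 833 lower). The share of higher calls was 49.2%, and 42.3% with library sizes alone, a scaling with which the median change of all genes was -0.08. Adjusted over the list alone, list counts were the same except for p53 targets (31 higher, 5 lower), luminal markers (14 higher, 3 lower), basal markers (13 higher, 1 lower) and ribosomal proteins (3 higher, 34 lower).

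**Figure D2:**
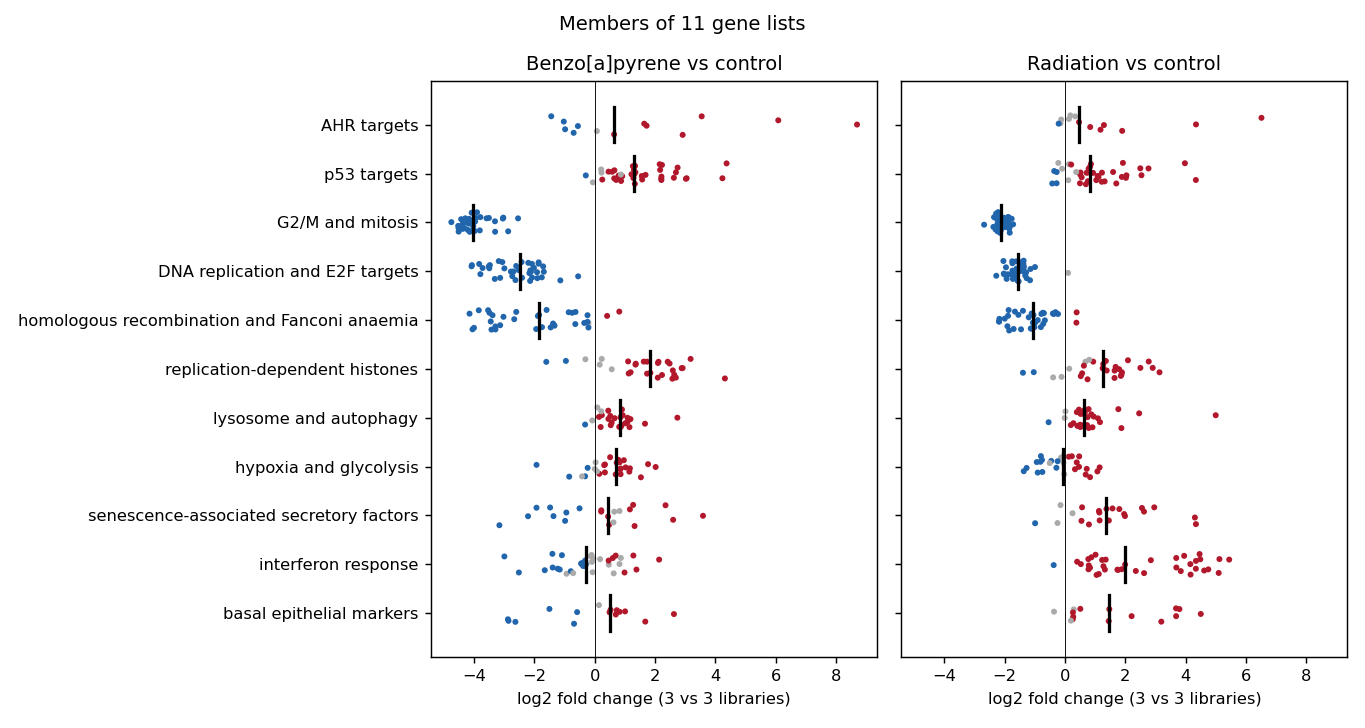
Log2 fold change of each measured member of 11 gene lists after benzo[a]pyrene (left) and after radiation (right), 3 libraries against 3. Red points rose and blue points fell with adjusted p under 0.05 in edgeR, grey points were not called, and black lines are list medians. The G2/M median was -4.04 after benzo[a]pyrene and -2.12 after radiation, and the interferon median was -0.28 and 2.00.

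Markers of cell types were compared because MCF7 is a luminal line. Luminal epithelial markers rose in 16 of 20 cases and fell in 2 after BaP (camera adjusted p = 3.51e-08), and rose in 13 and fell in 3 after radiation (camera adjusted p = 2.77e-05, and adjusted p = 0.0744 with an estimated correlation). TFF3 rose by 2.31 (SE 0.0873) after BaP and 1.18 (SE 0.0853) after radiation, and ELF3 by 2.23 (SE 0.074) and 2.84 (SE 0.0785). CLDN3 rose by 1.72 (SE 0.341) after BaP, with 9842 counts in BaP replicate 3 against 3118 and 3004, and by 0.88 without that library. Basal epithelial markers rose in 12 of 15 cases after radiation and fell in 0 (camera adjusted p = 5.07e-08). KRT16 rose by 3.79 (SE 0.118) and KRT15 by 3.68 (SE 0.183), and KRT14 had 2 counts over the control libraries against 48. After BaP 8 of the 15 rose and 6 fell (camera adjusted p = 0.248), and the median (0.49) and the mean (-0.16) differed in sign. KRT15 changed by 2.62 (SE 0.175), TP63 by -2.88 (SE 0.41) and KRT6A by -2.63 (SE 0.436), or -3.23 without BaP replicate 2. Of 5 measured fibroblast markers, 3 rose and 1 fell after BaP (camera adjusted p = 0.112) and 4 rose after radiation (camera adjusted p = 0.00394). VIM rose by 2.56 (SE 0.146) after BaP and 1.45 (SE 0.159) after radiation, and COL5A1 by 1.39 (SE 0.103) and 1.37 (SE 0.104). COL1A1, the marker that fell after BaP (-0.31, SE 0.132, adjusted p = 0.0498), lost its call with DESeq2 (adjusted p = 0.0603) and with RLE normalization (adjusted p = 0.0578). It also lost it with only the groups compared (adjusted p = 0.177) and without BaP control replicate 1 (adjusted p = 0.275), BaP replicate 1 (adjusted p = 0.155) or BaP replicate 2 (adjusted p = 0.222). COL6A3 rose by 0.73 (SE 0.219) after BaP, a call lost with libraries thinned to one depth (adjusted p = 0.0717). Epithelial-mesenchymal transition genes had 8 higher and 6 lower of 18 after BaP (camera adjusted p = 0.176). Among the lower, ZEB1 (-1.52, SE 0.535) lost its call without BaP control replicate 1 or 2 (adjusted p = 0.0875 and 0.0921) or BaP replicate 2 or 3 (adjusted p = 0.0553 and 0.0568). After radiation 13 were higher and 2 lower (camera adjusted p = 0.00276, and adjusted p = 0.051 with an estimated correlation). ACTA2, a smooth muscle actin, rose by 2.67 (SE 0.0705) after BaP and 1.63 (SE 0.0721) after radiation. Of 17 blood cell markers 4 were measured, and none rose after either exposure, while CORO1A changed by -2.02 (SE 0.0981) after BaP and -1.81 (SE 0.0951) after radiation.

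**Figure D3:**
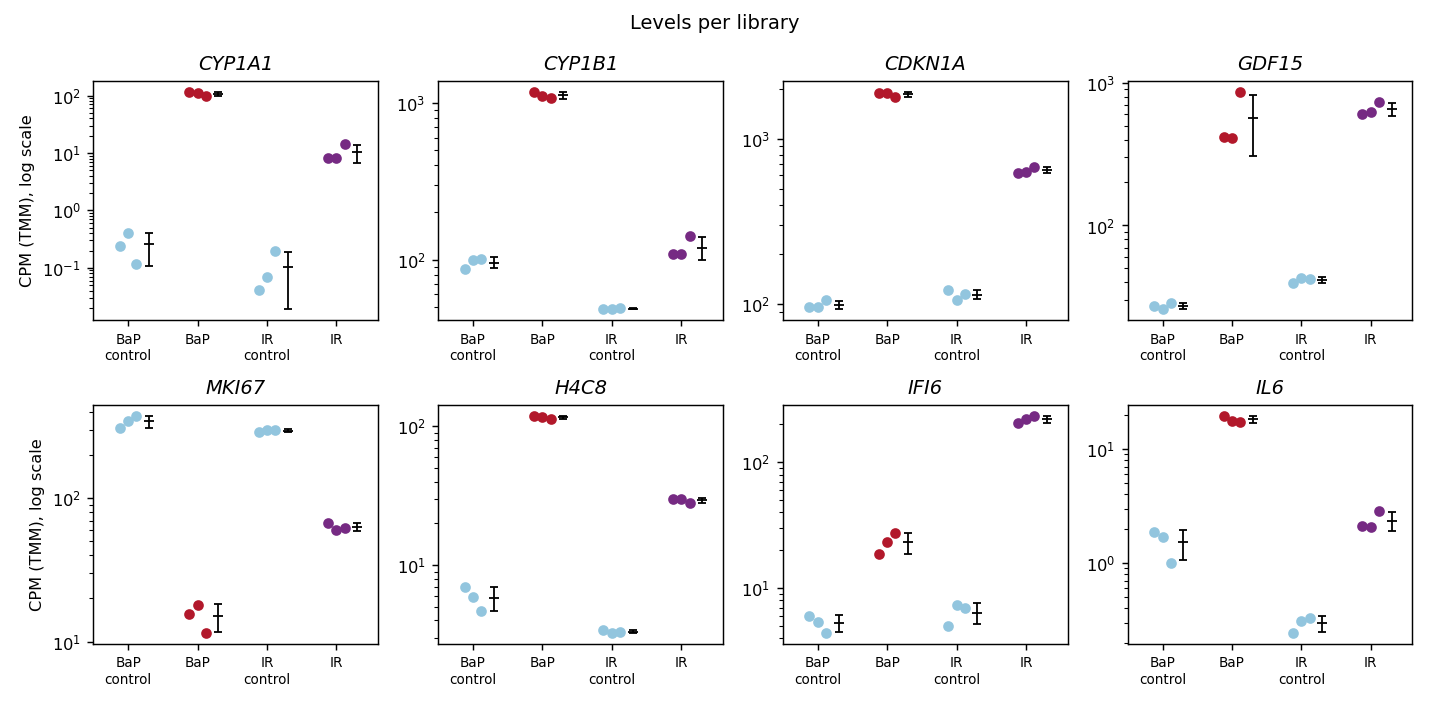
Normalized level of 8 genes in each of the 12 libraries, in CPM on a log axis. Coloured points are libraries, and the black mark beside each group is the mean with its SD (n = 3). CYP1A1 averaged 107 CPM in BaP and 10.2 CPM in IR, and IFI6 averaged 23.1 CPM in BaP and 221 CPM in IR.

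The test of the difference between the responses asked which genes changed more under one exposure than under the other, each against its own control. Each exposure had only 1 dose, so a difference between the agents cannot be told apart from one of dose or schedule. Of 37 interferon response genes 33 had a lower log2 change under BaP than under radiation and 0 a higher one, by a median of -2.46 (camera adjusted p = 1.51e-60). XAF1 differed by -6.16 (SE 0.657, adjusted p = 3.1e-06), and by -6.92 without BaP replicate 1. Secretory factors (13 of 21 lower, 1 higher, camera adjusted p = 3.16e-06) and basal markers (10 of 15 lower, 2 higher, camera adjusted p = 1.33e-05) also had lower changes under BaP. With an estimated correlation the basal markers had a camera adjusted p of 0.0344. Among the keratins, KRT6A differed by -5.83 (SE 0.48), or -6.42 without BaP replicate 2, and KRT17 by -5.19 (SE 0.515), or -4.52 without BaP control replicate 1. The other genes with the lowest values were the chemokine CCL22 (-5.75, SE 0.554), FOXI1 (-5.47, SE 0.237) and S100A8 (-5.32, SE 0.427). KRT6A had 2, 4 and 1 counts in the BaP libraries and CCL22 had 2, 3 and 6, so the size of these differences is uncertain.

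Division genes fell further under BaP. All 35 G2/M genes had a lower log2 change there (median difference -1.995, camera adjusted p = 4.42e-79), as did 37 of 38 replication genes (median -0.94, camera adjusted p = 1.03e-31). Of 35 recombination genes 25 were lower and 2 higher (median -0.75, camera adjusted p = 1.04e-13, and adjusted p = 0.0344 with an estimated correlation). MKI67 differed by -2.28 (SE 0.156), LMNB1 by -1.17 (SE 0.0852) and EXO1 by -2.15 (SE 0.175), while MSH2 (-0.06, SE 0.0963, adjusted p = 0.644) and MSH6 (0.03, SE 0.102, adjusted p = 0.827) were not called. The p53 targets rose further under BaP in 25 of 39 cases and less in 2 (median 0.48, camera adjusted p = 4.09e-10, and adjusted p = 0.0344 with an estimated correlation). CDKN1A differed by 1.73 (SE 0.0895), MDM2 by 1.30 (SE 0.0866) and DDB2 by 0.35 (SE 0.0805). Hypoxia and glycolysis genes had the higher change under BaP in 20 of 27 cases and the lower in 1 (median 0.56, camera adjusted p = 3.83e-11). Histones (8 higher, 1 lower of 29, median 0.42, camera adjusted p = 0.00671) and luminal markers (10 higher, 5 lower of 20, median 0.48, camera adjusted p = 0.0066) lost their calls with an estimated correlation (adjusted p = 0.192 and 0.296 with an estimated correlation). CYP1B1 differed by 2.25 (SE 0.13), TIPARP by 1.54 (SE 0.112), ESR1 by 0.90 (SE 0.0923) and TFF1 by 1.01 (SE 0.0887), and CYP1A1 was not called (2.18, SE 1.06, adjusted p = 0.112). The highest values were those of ENSG00000271732 (4.16, SE 0.659), IL17REL (4.11, SE 0.468), RGS22 (2.83, SE 0.361), PMP22 (2.80, SE 0.154), the T-cell inhibitor VTCN1 (2.65, SE 0.205) and ENSG00000273853 (2.46, SE 0.264). No other list was called for the difference, and for base excision repair, NRF2, apoptosis and lysosome genes the median, the mean and the direction of the test differed in sign. In total 7228 of 16943 genes were called by edgeR, 3778 with the higher and 3450 with the lower change under BaP, and 2015 differed at least 2-fold (322 higher, 1693 lower). The share of higher calls was 52.3%, but 46.8% with library sizes alone, 58.9% with DESeq2 and 57.3% without mitochondrial genes and the 10 genes with most counts, so which side is larger depends on the scaling. Adjusted over the list alone, 35 interferon genes, 26 recombination genes and 11 basal markers were lower and 3 basal markers higher, and the other counts given here were the same.

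Calls of the exposures overlapped. Both raised 3370 genes, where independent lists would share 1762, and both lowered 3616, where independent lists would share 1776.2 (Fisher's exact test, two-sided, odds ratios 7.22 and 9.92, each p at or below 1e-300, the smallest value written). Genes called in opposite directions numbered 913, against 3539.5 for independent lists. At a change of at least 2-fold, 1011 genes were higher and 645 lower under both, and 66 went in opposite directions. Log2 fold changes of the exposures correlated with Pearson's r of 0.633 and Spearman's rho of 0.629 across the 16943 genes, which are not independent replicates.

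**Figure D4:**
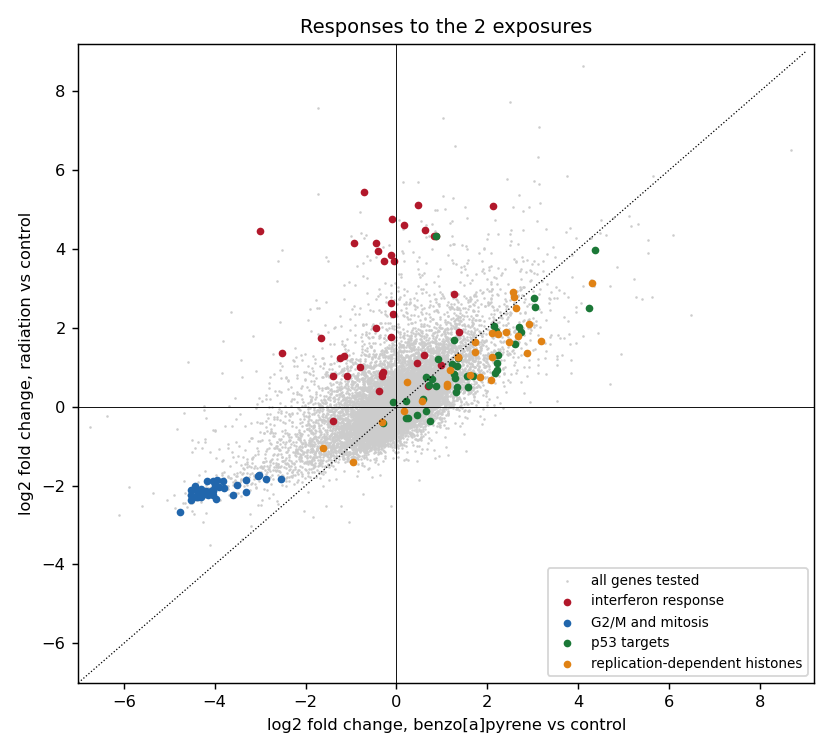
Log2 fold change after radiation (vertical) against that after benzo[a]pyrene (horizontal) for the 16943 genes tested, with 4 lists in colour and the line of equal change dotted. G2/M genes lie at a median of -4.04 horizontally and -2.12 vertically, and interferon genes at -0.28 and 2.00.

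The untreated control groups were compared because each exposure was set against its own control. Cytosolic ribosomal protein genes were higher in the radiation control in 46 of 53 cases and lower in 1 (median 0.55, camera adjusted p = 1.64e-23), and all 13 mitochondrially encoded genes were higher there (median 1.14, camera adjusted p = 6.76e-17). Estrogen receptor targets were lower there in 20 of 31 cases and higher in 5 (median -0.30, camera adjusted p = 0.00115). These calls were lost with an estimated correlation (adjusted p = 0.403, 0.403 and 0.486 with an estimated correlation). PALMD was at 0.422 ± 0.085 CPM in the BaP control and 2.28 ± 0.164 CPM in the radiation control (SD, n = 3), and CAPN8 (2.00, SE 0.177), GCGR (1.97, SE 0.266), ENSG00000260418 (2.31, SE 0.167), ENSG00000268649 (2.22, SE 0.341) and ENSG00000268903 (2.02, SE 0.579) were also higher in the latter. With GC and length trends removed ENSG00000268649 was at 1.448 and ENSG00000268903 at 1.13. HAPLN1 (-2.90, SE 0.213), COL12A1 (-2.65, SE 0.185), SLC9A4 (-2.59, SE 0.225), TMEM45A (-2.58, SE 0.152), S100A9 (-2.44, SE 0.171) and EDIL3 (-2.19, SE 0.246) were lower. Of 16943 genes 9550 were called by edgeR, 4679 higher and 4871 lower in the radiation control, and 1178 differed at least 2-fold (793 higher, 385 lower). The share of higher calls was 49.0%, and 35.2% with library sizes alone, a scaling with which the median change of all genes was -0.107. Log2 differences between the controls rose with GC content (Spearman's rho 0.407) and fell with exonic length (rho -0.342) across genes, and no label gives a batch, so the arm and any batch cannot be told apart.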

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

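Tests of the difference between the exposures, for genes and for lists with either correlation, were set before the data were examined. So were those of the number of genes called in other splits of the samples. All other tests in this part were chosen after the results they bear on had been seen. The 7228 genes whose response differs between benzo[a]pyrene (BaP) and radiation stand here because the difference itself passed a test between the exposures, as did the lists and genes that follow. Median differences of log2 changes, BaP minus radiation, were -2.46 for interferon response, -2.0 for G2/M and mitosis, -1.06 for basal epithelial markers, -0.96 for senescence-associated secretory factors, -0.94 for DNA replication, -0.75 for homologous recombination, 0.42 for histones, 0.48 for luminal markers, 0.48 for p53 targets and 0.56 for hypoxia and glycolysis. Histones and luminal markers lost their calls with an estimated correlation (adjusted p = 0.192 and 0.296 with an estimated correlation). Among genes the differences were -6.16 for XAF1, -5.83 for KRT6A, -5.75 for CCL22, -5.47 for FOXI1, -5.32 for S100A8, -5.19 for KRT17, -2.28 for MKI67, -2.15 for EXO1 and -1.17 for LMNB1. They were 0.35 for DDB2, 0.90 for ESR1, 1.01 for TFF1, 1.30 for MDM2, 1.54 for TIPARP, 1.73 for CDKN1A, 2.25 for CYP1B1, 2.46 for ENSG00000273853, 2.65 for VTCN1, 2.80 for PMP22, 2.83 for RGS22, 4.11 for IL17REL and 4.16 for ENSG00000271732.

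The count of 7228 was the highest of 60 drawn splits that exchanged exposed and control labels within the arms, 1 of the 60 counting the real one. The highest of the others was 5253. Such splits mix exposed and control libraries and so remove the effect of each exposure as well. They speak only against exchangeable labels within the arms and cannot decide whether the responses to BaP and radiation differ. Besides the real split, calls came from 9 splits, each of which kept 1 arm whole. For the other counts, 10 splits of 6 samples are too few for a share under 0.05: the real values were 11025 for BaP, 10877 for radiation and 9550 for the controls, each reached by 1 of its 10 splits, the real one, and the highest of the other splits was 0 in each.

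Of 37 interferon response genes 36 rose and 1 fell after radiation, while 7 rose and 15 fell after BaP. Starting levels differed: 14 of the 37 members were lower and 6 higher in the radiation control than in the BaP control (median -0.373). Among exposed cells 36 of the 37 were higher in irradiated than in BaP-exposed cells, with a median log2 ratio of 2.71. A different starting level is thus argued against as the whole cause. That ratio also holds the change after BaP and any difference between the arms. GC content and gene length are argued against as well, since with offsets for both the list's median change after radiation was 2.093, against 2.00 without them. Blood cells in the irradiated samples are argued against too: without CORO1A, which the line itself expresses (96.5% of the marker sum in the control), the other 16 blood cell markers went from 1.51 to 3.02 CPM in sum, a rise of 0.0986% of the 1532 CPM by which the interferon genes rose together. A response of the irradiated cells themselves also stays open, as a hypothesis found and tested on the same data.

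CYP1A1, which metabolizes BaP, rose in cells that were irradiated and not given BaP, to 10.2 CPM, at a ratio of 0.0746 to 0.134 to BaP-exposed cells over the irradiated libraries. Were RNA of BaP-exposed cells carried over, every gene would keep at least about that ratio, and 1 gene of at least 20 CPM in BaP-exposed cells, VTCN1, lay below it in all 3 irradiated libraries, at 0.0383 to 0.0583. A second version of the rule, tried after the first with a minimum of 5 CPM and the 95% upper counting limit of the ratio, also gave 1, where 3 genes had been set as needed to exclude carry-over, and the reading of fewer as undecided was set once the value was known. A further version, tried last, allowed for each gene's own control level in 109 genes at least 4-fold above it and gave 3, VTCN1, SLC26A2 and PMP22, but a fall of the cells' own expression could also place SLC26A2 and PMP22 there, so carry-over cannot be told apart from a response of the cells. AHR pathway activity in irradiated cells is a candidate explanation that stays open too: without CYP1A1, 6 of 12 AHR targets rose and 1 fell, with p = 0.104 for the set with an estimated correlation (camera) and p = 0.00775 with the preset one.

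A total of 9550 genes differed between the untreated controls. Trends with GC content and gene length are argued against as the whole cause, since 6547 of these genes were called in the same direction after both trends were removed, and the remaining genes of the 9550 were not. Library size was already scaled out in the main fit, so thinning can show only whether unequal depth mattered beyond that scaling. With all libraries thinned to one total, 9029 of the 9477 main calls present in both fits were called in the same direction. A larger share of mitochondrial transcripts in the radiation control would lower all other genes by one factor. The TMM scaling behind the 9550 calls already takes out such a factor, so the counts that follow cannot decide on those calls. With library sizes alone 3357 of the 4659 other genes called higher there stayed higher. With that scaling 6219 other genes were called lower, a set not drawn from the main calls. Of these, 5130 stayed lower with library sizes counted without mitochondrial genes, which argues against the share as the whole cause for that set. No label gives a batch, so a difference in time, culture or library preparation between the arms stays open, and no biological explanation was tested.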

How the results depend on the processing

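The offsets for GC content and length, the thinning, and the counts of lists and of shared genes without a library were chosen after the data were seen. All 4 counts of called genes stayed within 1.5 times the main value under every alternative run except the minimum change of 2-fold, which by construction keeps fewer genes: 3463 for BaP, 2951 for radiation, 2015 for the difference and 1178 for the controls, and 1656 in place of 6986 genes changed the same way by both exposures. Lists called by camera went from 16 to 6 for BaP, from 20 to 10 for radiation and from 3 to 0 for the controls with a correlation estimated per list, and from 10 to 8 for the difference. With fry, which does not compare a list with other genes, they were 26 for BaP, 18 for the difference and 17 for the controls. For the controls 5 lists were called with the GC trend removed and 5 with GC and length trends removed, against 3. The cause was not tested. Without 1 library in turn, counts ranged from 10187 to 10901 for BaP, 10064 to 10433 for radiation, 6238 to 8168 for the difference and 8286 to 9521 for the controls. Without BaP replicate 3 they were 10901 and 8168.

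Same-numbered replicates deviated together little or not at all (r of deviations from -0.2 to 0.074). In the radiation arm the same number had the highest r for replicates 1 and 2 (0.045 and 0.066). No clear pairing by number was seen, but low r cannot exclude one. With the replicate block 10895 genes were called for BaP, 10706 for radiation, 6904 for the difference and 9366 for the controls, and 15, 20, 11 and 4 lists, and 6873 genes changed the same way by both. Base excision repair after BaP had adjusted p = 0.0529 in that fit. A fit of only the groups compared has no counterpart for the difference, which uses all groups.

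Of the named-gene values under alternatives, 4742 kept direction and side of the threshold, 31 lost the call, 6 gained it and 5 turned sign, none of a gene called in the main analysis. POLH after BaP went to 0.12 with both control groups together, ranged from -0.127 to 0.018 without 1 library (the latter without BaP replicate 3) and went to 0.003 with GC and length trends removed. TIPARP and POLH after radiation went to -0.038 and -0.076 with both control groups together. Depth limits genes such as CXCL8, KRT14, TNF and RAD51, which have few counts in a group.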

Other observations

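The tests of this part were chosen after the patterns in other genes had been seen, but before the squamous genes or IFNB1 and IFNL1 had been looked at. The keratins KRT6A and KRT17 and the S100 gene S100A8 were among the 6 genes with the lowest difference between the responses, and squamous differentiation genes that had not been looked at were then tested as a list. Of 33 listed genes 20 were measured. Among these 16 rose and 0 fell after radiation (median 2.10), and 9 rose and 5 fell after BaP (median 0.39). Genes that passed the filter on low counts only through the irradiated libraries would count as rises, and their number was not examined. Between the untreated controls 6 were higher and 6 lower in the radiation control (median -0.168). Chosen after their values were seen, KLK5 and KLK6, skin-type proteases, rose by 3.34 (SE 0.146) and 3.12 (SE 0.127) after radiation and by 0.57 (SE 0.156) and 0.65 (SE 0.126) after BaP. CDSN, a desmosome protein, changed by 2.10 (SE 0.199) after radiation and -0.67 (SE 0.231) after BaP. The difference between the exposures had p = 0.0083 with an estimated correlation (camera), with 12 members lower and 1 higher for BaP minus radiation. This is consistent with the hypothesis that a squamous program may accompany the response to radiation more than that to BaP, and its independence from the difference between the control groups was not tested.

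A hypothesis for the interferon list is that irradiated cells transcribed interferon genes. The test asked for more than 10 counts of IFNB1 and IFNL1 together in each irradiated library and 3 or fewer in each control library. Over the 3 irradiated libraries they had 246 counts, 63 of IFNB1 and 183 of IFNL1, against 1 and 7 over the radiation control, 2 and 6 after BaP and 2 and 2 in the BaP control. The second condition failed, since radiation control replicate 2 held 1 count of IFNB1 and 5 of IFNL1, so the test as set did not decide. IFNL3 had 118 counts after radiation and 5 in its control. These values may point to autocrine signalling, which RNA levels alone cannot show.

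Irradiated libraries detected 25572 ± 346 genes with at least 1 count (SD, n = 3), against 23513 ± 430 in their control, and 3.13% ± 0.171 of nuclear counts fell in genes that are not protein-coding, against 2.00% ± 0.092. Log2 changes after radiation fell with expression level across genes (Spearman's rho -0.319).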
